A study of Homo sapiens with 18 samples.

How the data were processed

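RNA sequencing measured gene expression in human dermal microvascular endothelial cells (HMVEC-D) at passage 10. Cells at about 80% confluence received 50 nM of a miR-369-5p mimic, 50 nM of a control mimic based on the worm microRNA cel-miR-67, or no mimic, and were harvested 24 h or 48 h later. A microRNA mimic is a synthetic duplex that loads the silencing machinery and directs it to transcripts with a matching seed site. RNAiMAX, a lipid reagent, carried the mimics. The labels do not say whether untreated cells received the reagent alone. Each of the 6 groups held 3 libraries, 18 in all, made from total RNA with an Illumina TruSeq kit. Replicates are called biological in the labels with no further detail, so p-values of single genes measure the spread between these samples.

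The authors deposited 1 table of expected counts, 1 value per gene symbol and library, not scaled between libraries. Of the nonzero values, 86.6% lay within 0.01 of a whole number, and the rest were fractional. Expected counts were rounded to whole numbers for every test. The labels name the genome build GRCh38. The aligner, the quantifier and the annotation were not given in the sources used here. The table held 59428 gene symbols, of which 29498 had no count in the 18 libraries. A further 5 columns of the table matched no sample label and were not used here. Library totals ran from 29.9 to 37.35 M counts. The 10 most abundant genes took 7.92% to 10.1% of the counts of a library, and mitochondrially encoded transcripts took 4.3% to 5.91%.

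Gene symbols were matched to GENCODE 29, which placed 40217 of them. Positions given in the text are GRCh38 coordinates from that annotation. Genes that overlap another gene on the same strand over at least 20% of their exons are reported as uncertain where they are named, since the deposited counts cannot separate the reads. The same holds for genes with at least 50% of their exons under an antisense gene, as the labels do not state whether libraries were stranded.

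Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr by group, which left 16193 genes. Library factors came from the trimmed mean of M values (TMM) and ran from 0.952 to 1.03. The quasi-likelihood F test was run in 1 fit of all 18 libraries with the 6 groups as the only term. The common biological coefficient of variation was 0.155. The two-sided p-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 were called. Log2 fold changes are given with their standard error from the fit. Expression in CPM (counts per M counts, with M for mega) is given as group means over 3 libraries with the SD, after TMM scaling, and log2 CPM used a prior count of 2. Groups of 3 against 3 libraries fail to overlap in 10% of splits by chance.

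The comparisons were the miR-369-5p mimic against the control mimic at 24 h and at 48 h, the mean of both, the difference of the mimic effect between 48 h and 24 h, the control mimic against untreated cells at each time, and untreated cells at 48 h against 24 h. Comparisons that share a group of libraries are correlated by construction. Their overlaps were set against 20 simulations in which the groups had no difference, and against n1 × n2 / N, the product of the counts of calls over the number of genes tested. A shared group of 3 libraries cannot be split into parts of at least 2.

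Genes named in the text followed a rule fixed, like the comparisons, tests and gene lists, before the data were examined. Candidates were called, averaged at least 5 CPM, did not overlap between the groups compared, and were protein-coding with a symbol that is not clone-based. For the mimic against the control mimic at each time, the 10 largest changes in each direction were taken. For the mean of both times it was the 5 smallest p-values in each direction, and for the other comparisons the 5 largest changes in each direction. Each gene list added up to 4 called members with the largest absolute change and at least 5 CPM. A set of 20 genes of endothelial inflammation, clotting, tone and growth was followed whatever its values, and 19 of them are reported here (VCAM1, ICAM1, SELE, SELP, CCL2, CXCL8, IL6, EDN1, NOS3, HMOX1, F3, THBD, VWF, VEGFA, KDR, PECAM1, CDH5, PGF and ANGPT2). The 10 called genes with a miR-369-5p site of the 8mer or 7mer-m8 class and the lowest mean change were also taken.

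The 37 gene lists were endothelial identity, lymphatic endothelial markers, leukocyte adhesion and NF-kB inflammation, type I interferon response, vascular tone and vasoactive signalling, coagulation and fibrinolysis, heme and NRF2 oxidative stress response, hypoxia and glycolysis, VEGF, Notch and tip-cell angiogenesis, TGF-beta/BMP signalling, extracellular matrix, endothelial-to-mesenchymal markers, cytoskeleton and SRF/YAP targets, adherens and tight junctions, S phase and DNA replication, G2/M and mitosis, replication-dependent histones, p53 targets, senescence-associated secretion and growth arrest, cholesterol biosynthesis and SREBP2, LXR and lipid efflux, unfolded protein and integrated stress response, heat shock response, immediate early genes, apoptosis regulators, autophagy and lysosome, cytosolic ribosomal proteins, ribosome biogenesis and MYC targets, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, small RNA silencing machinery, RNA and DNA sensing, and markers of fibroblasts, pericytes and smooth muscle, keratinocytes, leukocytes, and melanocytes and Schwann cells. They came from general knowledge, and some genes stand in several lists. Lists were tested with camera (limma 3.58.1) on voom weights with a preset correlation of 0.01, adjusted over the lists of a comparison. Lists with fewer than 5 tested members had no test. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes moved one way on balance and compares it with no other genes. List results in the text are medians of log2 fold changes, with the adjusted p of camera.

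Seed sites were searched in the longest annotated 3′ UTR of each gene. A UTR was annotated for 18882 genes, of which 13062 were tested. Sequences of hsa-miR-369-5p (AGAUCGACCGUGUUAUAUUCGC), hsa-miR-369-3p (AAUAAUACAUGGUUGAUCUUU) and cel-miR-67 (UCACAACCUCCUAGAAAGAGUAGA) came from general knowledge and were not given in the labels. Genes with an 8mer or 7mer-m8 site were set against genes with no site of any class. The median log2 fold change was compared with 10000 random lists of the same size from genes with no site, matched in 5 bins of UTR length by 5 bins of expression. Permutation p-values are two-sided, and 0.0001 is the smallest they can give. All 16384 7-mers were also ranked by the change of the genes that hold them, after regression on log2 UTR length, GC content and expression. That regression was chosen after seeing the data. A 7-mer needed at least 30 genes, and 16369 had them.

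Alternatives were other scaling factors (DESeq2 size factors, upper quartile, library totals alone), no filter and a stricter filter (1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, fits of the groups compared only, a replicate block, an adjusted p under 0.01, an absolute log2 fold change of at least 1, untreated cells as the reference, other site classes and UTRs, and omission of each library in turn. An offset that removes the trend of each library along transcript length and GC content (natural splines) was added after seeing that replicates differed along transcript length. Length and GC content were known for 14678 tested genes, or 90.6%.

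The edgeR fit was tested on simulated data of the same size. It called 46.3% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 98.5% of those changed 4-fold, and 4.8% of its 166 calls were unchanged genes. The list test called 1 list where 1 was shifted. A simulated length trend of 0.5 on the log2 scale per SD of log2 length gave 4927 calls before the offset and 0 after it. The seed test made 6 false calls in 100 draws, recovered -0.192 where -0.2 was put in (100 calls) and -0.0809 where -0.1 was (51 calls). The test of 24 seeds together made 8 false calls in 100 draws. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for tables, sequence searches and plots.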

Results

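Gene expression was measured in human dermal microvascular endothelial cells, the lining cells of small skin vessels, 24 h and 48 h after transfection of a miR-369-5p mimic. The series asks how this microRNA changes endothelial gene expression, with sickle cell disease complications as the stated background. Cells with a control mimic and untreated cells served as references, and each of the 6 groups held 3 libraries. In the order of replicates 1 to 3, untreated libraries held 34.66, 37.35 and 36.18 M counts at 24 h and 30.86, 35.94 and 33.77 M at 48 h. Control mimic libraries held 36.23, 32.42 and 29.9 M counts at 24 h and 32.55, 31.72 and 33.19 M at 48 h. Libraries of the miR-369-5p mimic held 35.66, 34.33 and 34.95 M counts at 24 h and 31.16, 31.17 and 31.64 M at 48 h.

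Libraries differed along transcript length, with groups and replicates on different slopes. The slope of log2 CPM, as a deviation from each gene's mean, was -0.25 to -0.187 per SD of log2 transcript length in mimic libraries at 24 h, and -0.0864 to 0.147 in control mimic libraries. At 48 h it ran from -0.124 to 0.164 in mimic libraries and from 0.167 to 0.195 in control mimic libraries. Untreated libraries spanned -0.136 to 0.00981 at 24 h and -0.147 to 0.207 at 48 h. A lower slope means that short transcripts, such as those of most ribosomal proteins, were relatively higher.

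**Figure D1:**
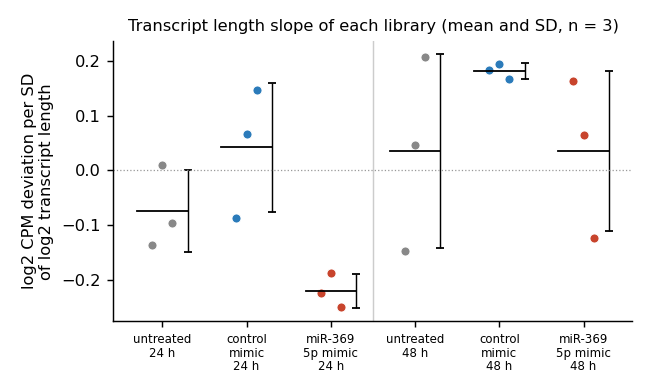
Slope of log2 CPM, as a deviation from each gene's mean, on log2 transcript length in SD units, for each of the 18 libraries (points) by group. Mimic libraries at 24 h lie at -0.25 to -0.187, below all 3 control mimic libraries of that time, and untreated libraries at 48 h spread from -0.147 to 0.207.

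The first comparison asked what the miR-369-5p mimic changed beyond a control mimic at 24 h. Genes of DNA replication and cell division were lower with the mimic, and genes with a seed site for the control mimic were higher. Heme and NRF2 response genes, interferon response genes, ribosomal protein genes and oxidative phosphorylation genes also rose as lists, but these 4 calls were lost with an estimated correlation (adjusted p = 0.62 each). Of 16193 genes, 3132 rose and 3372 fell, 6504 in all.

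Cell division genes had the largest median change of the 37 lists at 24 h. Of 73 measured G2/M and mitosis genes, 66 fell (68 adjusted over the list alone), with a median log2 fold change of -1.34 and an adjusted p of 8.33e-41. This call held with an estimated correlation (adjusted p = 0.0472). The topoisomerase TOP2A (chromosome 17, 40388516 to 40417950), which untangles chromosomes before division, went from 169.7 ± 24.7 CPM to 37.0 ± 5.21 CPM (SD, n = 3 each), a log2 fold change of -2.20 ± 0.22 (adjusted p 3.6e-06). The spindle genes KIF14 (-2.23 ± 0.24) and ASPM (-2.12 ± 0.30) and the cytokinesis gene ANLN (-2.12 ± 0.21) fell likewise. Among 58 S phase and DNA replication genes, 47 fell (48 adjusted over the list alone), with a median of -0.95 and an adjusted p of 3.31e-25, or adjusted p = 0.00889 with an estimated correlation. CLSPN, a replication checkpoint gene, fell by 2.07 ± 0.21 on the log2 scale, the cyclin gene CCNE2 by 2.02 ± 0.22 and the replisome gene GINS1 by 1.99 ± 0.15. Outside the lists, ZNF367 (-2.52 ± 0.20), FAM111B (-2.23 ± 0.16) and TNFSF15, an endothelial cytokine of the TNF family (-2.17 ± 0.21), were among the 10 largest falls. Against untreated cells at 24 h, TOP2A stood at -1.39 and TNFSF15 at -1.47, and medians were -0.99 for G2/M and -0.87 for S phase genes. Replication-dependent histones had no call (3 of 21 rose, 2 over the list alone; median 0.39, adjusted p 0.226).

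Of the 10 largest rises at 24 h, 5 were genes with a cel-miR-67 8mer or 7mer-m8 site in the 3′ UTR, namely GPSM3, CHST14, MNAT1, NARS2 and POP5. CHST14 (chromosome 15, 40470998 to 40474571), a sulfotransferase of dermatan sulfate synthesis, stood at 41.3 ± 1.52 CPM untreated, 12.6 ± 0.623 CPM with the control mimic and 43.0 ± 2.97 CPM with the miR-369-5p mimic. Its log2 fold change was 1.77 ± 0.10 between the mimics (adjusted p 2.6e-08) and 0.06 against untreated cells. GPSM3 (chromosome 6, 32190766 to 32195523), a regulator of G protein signalling, rose by 1.87 ± 0.16 over the control mimic and stood at 0.38 over untreated cells. MNAT1 rose by 1.68 ± 0.15, NARS2 by 1.45 ± 0.14 (-0.21 against untreated cells) and POP5 by 1.41 ± 0.20. NDUFB5, a respiratory complex I subunit with no such site, rose by 1.82 ± 0.17, and was at 69.6 CPM untreated, 24.3 CPM with the control mimic and 86.2 CPM with the miR-369-5p mimic. CA2, a carbonic anhydrase, rose by 1.79 ± 0.17 and MARCKSL1 by 1.52 ± 0.15. The remaining large changes were uncertain, as CDRT4 (1.71), MRPS24 (1.57), ZBED6 (-8.05), TMX2-CTNND1 (-7.60) and FMC1-LUC7L2 (-3.94) share 23.2% to 100% of their exons with another gene.

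**Figure D2:**
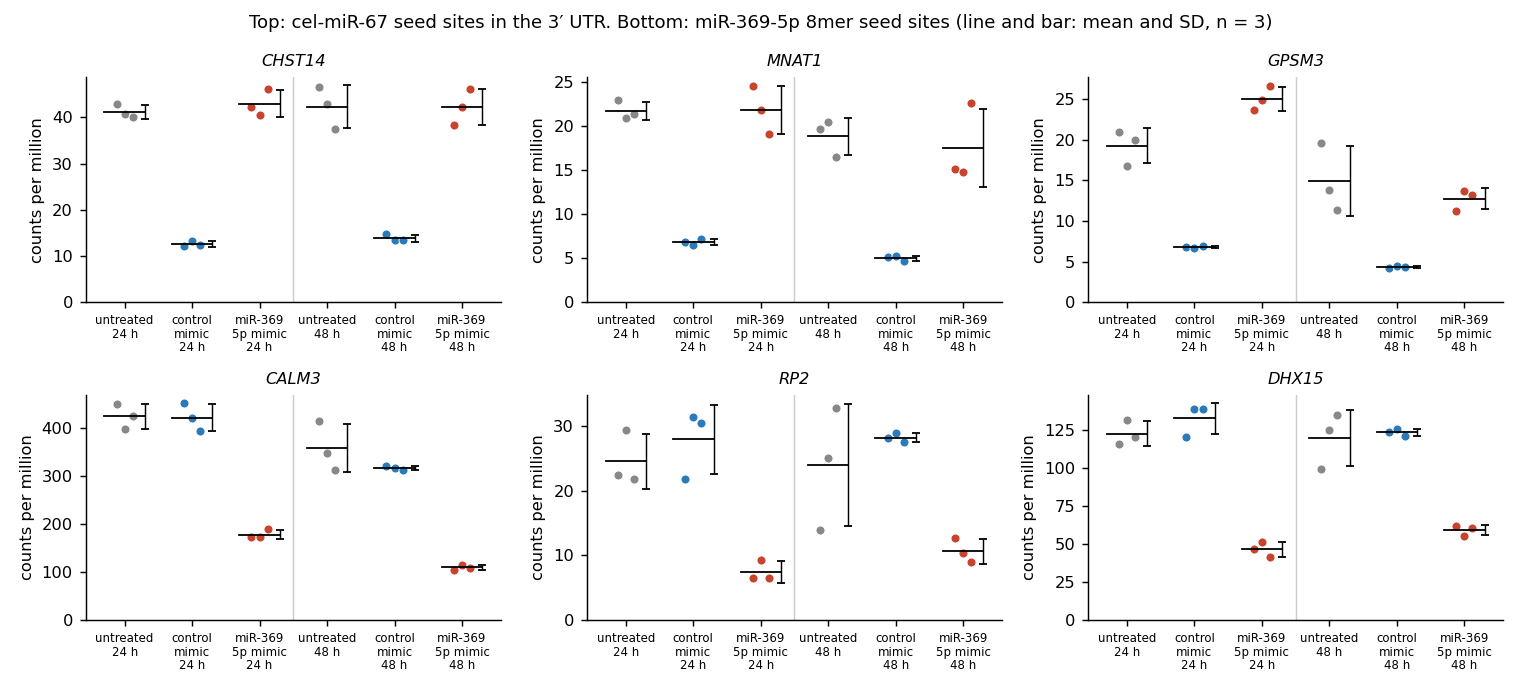
Expression in CPM of 3 genes with a cel-miR-67 site (top) and 3 genes with a miR-369-5p 8mer (bottom) in each library (points), with the mean (line) and SD (bar) of each group of 3. CHST14 averages 12.6 and 13.9 CPM in the control mimic groups and 41.3 to 43.0 CPM in the other 4 groups, and CALM3 averages 178.4 and 110.0 CPM in the mimic groups and 316.8 to 424.9 CPM elsewhere.

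Heme and NRF2 oxidative stress response genes rose as a list at 24 h, with 17 of 35 up and 3 down (18 and 5 adjusted over the list alone), a median of 0.43 and an adjusted p of 0.00608, or adjusted p = 0.62 with an estimated correlation. Its median was 0.10 (adjusted p 0.0446) with the length and GC trend removed. HMOX1 (chromosome 22, 35380361 to 35394214) rose from 93.3 ± 5.42 CPM to 238.1 ± 25.2 CPM, a log2 fold change of 1.35 ± 0.13, and the oxidoreductase AKR1C1 rose by 1.08 ± 0.18. HMOX1 was at 138.2 ± 14.1 CPM in untreated cells. Type I interferon response genes rose in 17 of 47 cases (17 over the list alone), with a median of 0.26 and an adjusted p of 0.0187. That call was lost with an estimated correlation (adjusted p = 0.62) and without mimic replicate 2 (adjusted p 0.128). ISG15, a ubiquitin-like antiviral protein, rose by 1.12 ± 0.25 and the transcription factor IRF7 by 1.01 ± 0.16. Autophagy and lysosome genes rose in 24 of 51 cases and fell in 2 (26 and 2 over the list alone; median 0.26, adjusted p 0.00116, adjusted p = 0.62 with an estimated correlation; median 0.14 with the trend removed). The lysosomal cholesterol carrier NPC2 rose by 0.75 ± 0.16, while the autophagosome protein MAP1LC3B fell by 0.77 ± 0.10.

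All 78 cytosolic ribosomal protein genes rose at 24 h (78 over the list alone), with a median of 0.73 and an adjusted p of 1.17e-16, but adjusted p = 0.62 with an estimated correlation. Oxidative phosphorylation genes rose in 55 of 72 cases and fell in 2 (64 and 2 over the list alone), with a median of 0.66 and an adjusted p of 9.22e-13, or adjusted p = 0.62 with an estimated correlation. Both lists moved with the length slope, which was lower in mimic libraries by the values given above. With the length and GC trend removed the medians were 0.39 and 0.23. Small RNA silencing genes fell in 18 of 31 cases and rose in 1 (19 and 1 over the list alone), with a median of -0.37 and an adjusted p of 0.000875, or adjusted p = 0.62 with an estimated correlation. AGO2, the slicing Argonaute, fell by 1.12 ± 0.25 and DICER1 by 1.06 ± 0.31, but against untreated cells they stood at -0.19 and 0.09. This list too moved with the length slope, and its median was -0.17 (adjusted p 0.0563) with the trend removed. Cholesterol biosynthesis genes fell in 15 of 32 cases and rose in 2 (16 and 2 over the list alone; median -0.30, adjusted p 0.0187). That call was lost with an estimated correlation (adjusted p = 0.62) and without control mimic replicate 1 (adjusted p 0.135). The fatty acid synthase FASN fell by 0.96 ± 0.20.

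Of 19 genes reported from the set followed in every comparison, 7 changed at 24 h. The junction cadherin CDH5 (-0.65 ± 0.12), the anticoagulant receptor THBD (-0.62 ± 0.14), the growth factor VEGFA (-0.51 ± 0.12) and its receptor KDR (-0.65 ± 0.20) fell. HMOX1, PGF (0.54 ± 0.18) and the platelet and leukocyte adhesion receptor SELP (0.28 ± 0.11) rose. The other 12 had no call, with log2 fold changes from -0.32 (F3) to 0.33 (CXCL8). Endothelial identity genes went both ways (11 of 40 up and 8 down, 13 and 8 over the list alone; median 0.12, adjusted p 0.646), with SOX18 and CLDN5 each at 1.20. TGF-beta/BMP genes fell in 19 of 36 cases and rose in 5, short of a list call (median -0.38, adjusted p 0.0509). INHBA, an activin subunit, fell by 1.23 ± 0.22.

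Of the further lists at 24 h, none had a call, and their counts of rises and falls follow with the adjusted p of the list. Removing the length and GC trend brought calls of ribosome biogenesis (-0.24, adjusted p 4.4e-05), cytoskeleton (-0.23, 0.0048) and TGF-beta/BMP genes (-0.32, 0.0157). Lymphatic markers had 4 and 2 of 20 (0.705), NF-kB inflammation 9 and 5 of 41 (0.705), vascular tone 6 and 3 of 36 (0.626), coagulation 4 and 7 of 30 (0.229), hypoxia and glycolysis 12 and 9 of 41 (0.51), and VEGF and Notch angiogenesis 10 and 9 of 41 (0.883). Extracellular matrix had 5 and 14 of 52 (0.14), endothelial-to-mesenchymal markers 5 and 5 of 19 (0.646), cytoskeleton and SRF/YAP targets 7 and 16 of 38 (0.15), and junctions 7 and 13 of 32 (0.215). P53 targets had 10 and 7 of 41 (0.705), senescence 7 and 7 of 24 (0.705), LXR 6 and 3 of 14 (0.607), the unfolded protein response 12 and 8 of 49 (0.384), heat shock 2 and 3 of 25 (0.78), immediate early genes 11 and 6 of 38 (0.226) and apoptosis 9 and 11 of 35 (0.646). Ribosome biogenesis had 3 and 15 of 43 (0.0869), mitochondrially encoded transcripts 6 and 3 of 15 (0.226), and RNA and DNA sensing 5 and 2 of 20 (0.705). Adjusted over the list alone, the counts were 8 and 4 for NF-kB inflammation, 5 and 3 for vascular tone, 2 and 7 for coagulation, 15 and 9 for hypoxia, 11 and 9 for angiogenesis, 5 and 8 for mesenchymal markers, 9 and 14 for junctions, 9 and 9 for senescence, 13 and 8 for the unfolded protein response, 16 and 6 for immediate early genes, 10 and 11 for apoptosis, 7 and 3 for mitochondrially encoded transcripts and 6 and 4 for sensing, and as above for the others. Median and test differed in sign for lymphatic, p53, heat shock and sensing genes, and median and mean for senescence genes. Markers of other cell types had no call either, with medians of 0.22 for fibroblasts (adjusted p 0.706), 0.44 for pericytes (0.51), 0.19 for keratinocytes (0.731) and 0.53 for leukocytes (0.116). Melanocyte and Schwann cell markers, with 4 members measured, had no test (median -0.15).

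The count at 24 h fell to 3407 without control mimic replicate 3, to 3715 without control mimic replicate 2 and to 3776 without mimic replicate 3. With untreated cells as the reference it was 1108, and 935 of the 6504 calls were called in the same direction and 8 in the opposite one.

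At 48 h the same comparison showed interferon response genes far above the control mimic, and cell division genes far below it. The antiviral GTPase MX1 (chromosome 21, 41420304 to 41459214) rose from 23.4 ± 3.55 CPM to 241.9 ± 36.2 CPM (SD, n = 3 each). The hyaluronan receptor CD44 (chromosome 11, 35138870 to 35232402) fell from 174.1 ± 16.4 CPM to 27.7 ± 2.87 CPM. Lists of TGF-beta/BMP, matrix, cytoskeletal and mesenchymal genes fell, and heme and NRF2 response genes rose. Of the lists named so far, interferon alone kept its call with an estimated correlation (adjusted p = 0.015), where G2/M genes had 0.0547, S phase genes 0.461 and the other 5 lists 0.0547 to 0.453. Against untreated cells the calls of matrix (-0.05, adjusted p 0.187), mesenchymal (-0.17, 0.522) and heme genes (0.15, 0.0912) ended. In all 2165 genes rose and 2513 fell, 4678 together.

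Of 47 interferon response genes, 45 rose at 48 h (46 over the list alone), with a median of 1.6 and an adjusted p of 2.3e-36. IFIT1 (chromosome 10, 89392546 to 89406486), which binds foreign RNA, rose from 3.84 ± 0.48 CPM to 59.7 ± 5.08 CPM, a log2 fold change of 3.96 ± 0.34 (adjusted p 3.4e-07), against 2.29 CPM in untreated cells. MX2 (3.70 ± 0.38), MX1 (3.37 ± 0.27), IFIT3 (3.02 ± 0.20), the chemokine CXCL11 (2.93 ± 0.15), IFI44L (2.89 ± 0.23), ISG15 (2.70 ± 0.26) and IFI6 (2.61 ± 0.31) rose with it. IFITM1 (3.41 ± 0.24) shares 32.5% of its exons with IFITM2 and is uncertain. Against untreated cells, the list's median was 1.58, with IFIT1 at 4.70 and MX1 at 4.34. RNA and DNA sensing genes, several of which stand in both lists, rose in 11 of 20 cases (11 over the list alone; median 0.43, adjusted p 8.05e-07, adjusted p = 0.119 with an estimated correlation), led by OAS3 (2.32 ± 0.24) and OAS1 (1.93 ± 0.15).

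**Figure D3:**
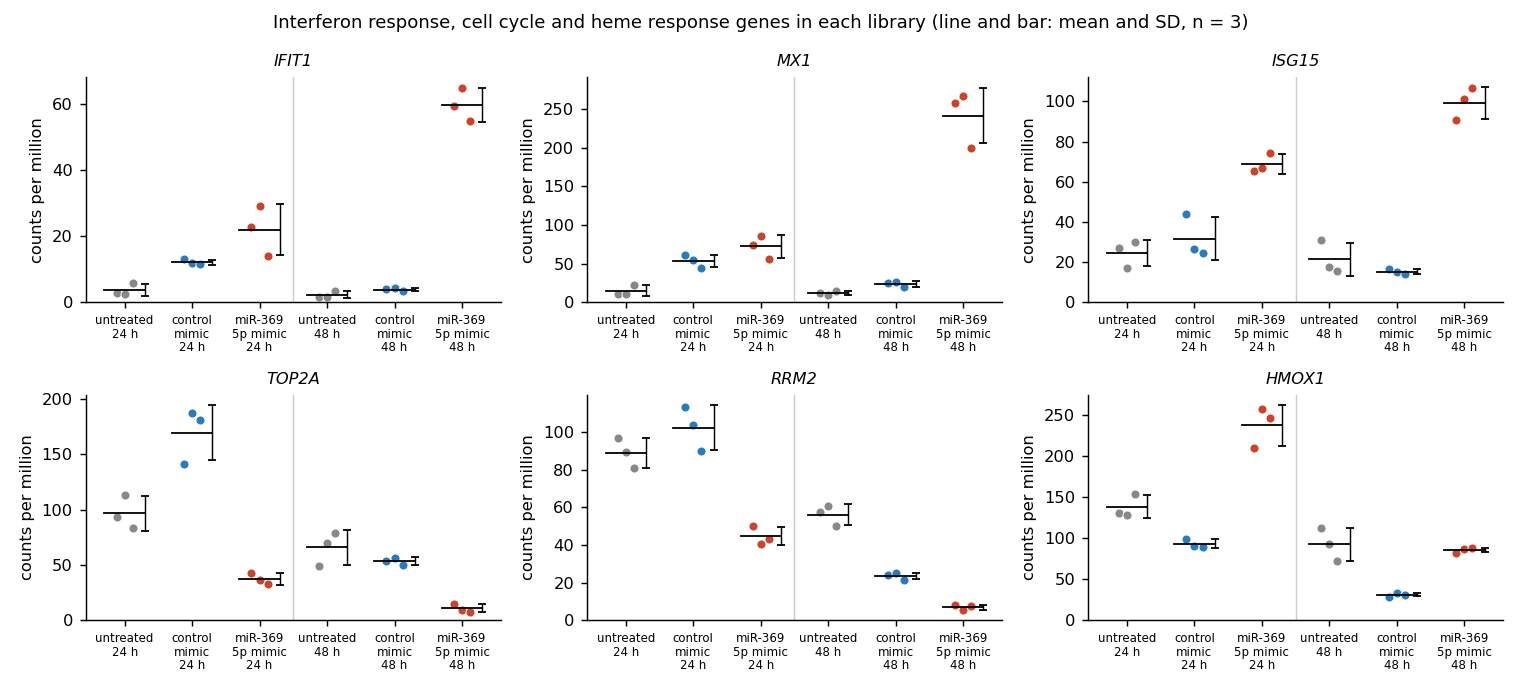
Expression in CPM of 3 interferon response genes, 2 cell cycle genes and HMOX1 in each library (points), with the mean (line) and SD (bar) of each group of 3. MX1 averages 241.9 CPM with the miR-369-5p mimic at 48 h and 11.97 to 72.3 CPM in the other 5 groups, and TOP2A averages 10.6 CPM there against 37.0 to 169.7 CPM elsewhere. RRM2 shares 20.2% of its exons with another gene.

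Of the 73 G2/M genes, 62 fell and 1 rose at 48 h (65 and 1 over the list alone), with a median of -1.58 and an adjusted p of 1.42e-30, or adjusted p = 0.0547 with an estimated correlation. TOP2A (-2.33 ± 0.22), the kinetochore gene CENPF (-2.33 ± 0.23), KIF18B (-2.35 ± 0.18), DEPDC1 (-2.43 ± 0.17), IQGAP3 (-2.41 ± 0.22) and the proliferation marker MKI67 (-2.29 ± 0.29) fell. S phase genes fell in 24 of 58 cases and rose in 8 (30 and 11 over the list alone; median -0.37, adjusted p 0.0131, adjusted p = 0.461 with an estimated correlation). Against untreated cells at 48 h the medians were -2.36 for G2/M and -1.31 for S phase genes.

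At 48 h TNFSF15 fell by 3.02 ± 0.22, CD44 by 2.65 ± 0.12 (adjusted p 4.2e-09), the collagenase MMP1 by 2.43 ± 0.14, the mitochondrial carrier UCP2 by 2.33 ± 0.15 and the growth factor receptor EGFR by 2.33 ± 0.26. TGF-beta/BMP genes fell in 21 of 36 cases and rose in 4 (23 and 4 over the list alone; median -0.53, adjusted p 9.83e-05, adjusted p = 0.12 with an estimated correlation), among them INHBA (-2.08 ± 0.22) and the TGF-beta target PMEPA1 (-1.67 ± 0.14). Extracellular matrix genes fell in 21 of 52 cases and rose in 7 (21 and 8 over the list alone; median -0.40, adjusted p 0.000351, adjusted p = 0.453 with an estimated correlation), including the gelatinase MMP2 (-1.50 ± 0.09) and the collagen gene COL1A2 (-1.39 ± 0.11), while fibulin FBLN2 rose by 1.58 ± 0.18. Endothelial-to-mesenchymal markers fell in 8 of 19 cases and rose in 2 (9 and 3 over the list alone; median -0.31, adjusted p 0.0031, adjusted p = 0.0547 with an estimated correlation), with the transcription factor ZEB2 at -1.39 ± 0.23. Cytoskeleton and SRF/YAP targets fell in 15 of 38 cases and rose in 1 (15 and 2 over the list alone; median -0.29, adjusted p 0.000301, adjusted p = 0.0547 with an estimated correlation), with the receptor kinase AXL at -1.32 ± 0.15. Junction genes fell in 14 of 32 cases and rose in 5 (15 and 5 over the list alone; median -0.24, adjusted p 0.0231), with the connexin GJA1 at -1.37 ± 0.10. That call was lost with an estimated correlation (adjusted p = 0.453) and with the length and GC trend removed (median -0.21, adjusted p 0.0584).

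Heme and NRF2 genes rose in 18 of 35 cases and fell in 2 at 48 h (19 and 2 over the list alone; median 0.51, adjusted p 1.57e-05, adjusted p = 0.223 with an estimated correlation). HMOX1 rose from 30.9 ± 2.14 CPM to 85.5 ± 2.88 CPM (1.47 ± 0.13), and stood at 92.4 ± 19.7 CPM in untreated cells, -0.11 on the log2 scale. AKR1C1 (1.50 ± 0.18) and AKR1C2 (1.47 ± 0.22) rose too. Coagulation genes fell in 14 of 30 cases and rose in 4 (14 and 5 over the list alone, median -0.29, adjusted p 0.0176), with the receptor gene F2RL1 at -2.18 ± 0.14 and the plasminogen activator PLAU at -1.34 ± 0.12. This call was lost with an estimated correlation (adjusted p = 0.12) and with the length and GC trend removed (median -0.27, adjusted p 0.0856). The coagulation inhibitor TFPI2 rose by 1.55 ± 0.10 over the control mimic but stood at -0.54 against untreated cells (adjusted p 8.90e-04). Of the 19 reported followed genes, 10 changed at 48 h. CDH5 (-0.96 ± 0.12), VEGFA (-0.79 ± 0.12), THBD (-0.79 ± 0.15), the cytokine IL6 (-1.20 ± 0.34), ICAM1 (-0.48 ± 0.09) and the vasoconstrictor gene EDN1 (-0.26 ± 0.09) fell, and HMOX1, VCAM1 (0.78 ± 0.17), CXCL8 (0.93 ± 0.18) and SELP (0.33) rose. CXCL8 was at -0.18 against untreated cells. NF-kB inflammation genes went both ways (13 of 41 up, 11 down; 14 and 11 over the list alone; median 0.11, adjusted p 0.475), with the alarmin IL33 up by 1.43 ± 0.22.

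Several called lists at 48 h rested on single libraries. Without mimic replicate 3, the calls ended for ribosomal proteins (median 0.32 and adjusted p 0.000575 with it, median 0.02 and adjusted p 0.798 without it), oxidative phosphorylation (0.34 and 9.2e-05, adjusted p 0.126 without it), autophagy (0.17 and 0.0258, then 0.0797) and the silencing machinery (-0.26 and 0.0231, then 0.126). Senescence genes (3 of 24 up, 12 down, 4 and 12 over the list alone; median -0.40, adjusted p 0.0366) lost their call without mimic replicate 1 (adjusted p 0.0815) and cholesterol genes (1 of 32 up, 12 down, 1 and 13 over the list alone; median -0.19, adjusted p 0.0259) without control mimic replicate 1 (adjusted p 0.0677). Individually, 1 of 78 ribosomal protein genes and 7 of 72 oxidative phosphorylation genes rose (6 of the latter over the list alone), 18 of 51 autophagy genes rose and 6 fell (20 and 7), and 3 of 31 silencing genes rose and 10 fell (3 and 11). Mitochondrially encoded transcripts rose in 8 of 15 cases (10 over the list alone; median 0.36, adjusted p 0.0031). With an estimated correlation these 7 lists had adjusted p-values of 0.81, 0.798, 0.495, 0.702, 0.453, 0.581 and 0.223, in that order. Mimic libraries at 48 h had a lower length slope than control mimic libraries, and with the trend removed the calls also ended for ribosomal proteins (median 0.09, adjusted p 0.178), the silencing machinery (-0.15, 0.0856) and mitochondrially encoded transcripts (0.08, 0.578), while oxidative phosphorylation stood at 0.12 (0.0411).

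The remaining lists had no call at 48 h. Rises and falls were 4 and 11 of 40 for endothelial identity (adjusted p 0.528), 5 and 3 of 20 for lymphatic markers (0.209), 6 and 11 of 36 for vascular tone (0.899), 9 and 13 of 41 for hypoxia (0.528) and 5 and 16 of 41 for VEGF and Notch angiogenesis (0.0785). CD34 rose by 1.32 ± 0.20 (-0.14 against untreated cells) and the flow-responsive factor KLF2 fell by 1.25 ± 0.23. P53 targets had 6 and 9 of 41 (0.628), the unfolded protein response 8 and 10 of 49 (0.98), apoptosis 3 and 9 of 35 (0.326), immediate early genes 9 and 11 of 38 (0.859), LXR 3 and 3 of 14 (0.846), heat shock 4 and 2 of 25 (0.605) and ribosome biogenesis 6 and 4 of 43 (0.846), and 2 of 21 histones fell (0.665). Adjusted over the list alone, the counts were 10 and 13 for hypoxia, 6 and 20 for angiogenesis, 6 and 11 for p53 targets, 10 and 12 for immediate early genes and 3 and 2 for heat shock. Median and test differed in sign for endothelial identity, vascular tone, immediate early genes and pericyte markers. Markers of fibroblasts (median 0.27, adjusted p 0.963), pericytes (0.16, 0.846), keratinocytes (-0.15, 0.577) and leukocytes (0.87, 0.11) had no call. With untreated cells as the reference the count was 2212, and 1313 of the 4678 calls were called in the same direction and 90 in the opposite one.

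**Figure D4:**
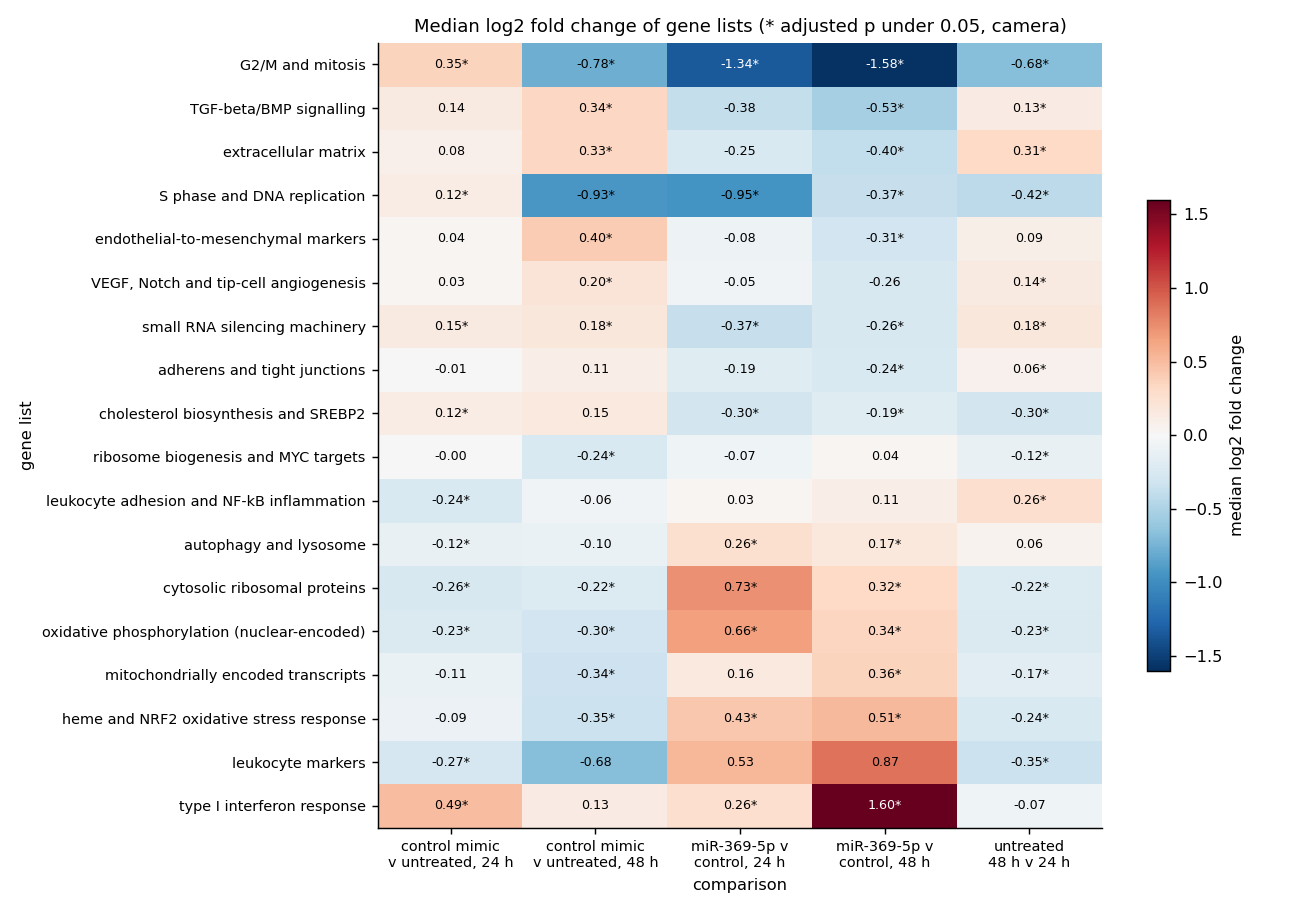
Median log2 fold change (colour and number) of the gene lists called in at least 2 of the 5 comparisons shown. Asterisks mark an adjusted p under 0.05 by camera with a preset correlation. The interferon response reaches 1.6 with the mimic at 48 h, and G2/M genes stand at -1.34 and -1.58 with the mimic.

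The mean over both times asked which effects of the mimic held at 24 h and 48 h together, and whether genes with a miR-369-5p seed site fell. Genes with such a site were lower than matched genes without one. CALM3 (chromosome 19, 46601074 to 46610793), 1 of 3 calmodulin genes and carrier of an 8mer, went from 422.5 ± 28.8 CPM to 178.4 ± 9.61 CPM at 24 h and from 316.8 ± 4.49 CPM to 110.0 ± 5.39 CPM at 48 h (SD, n = 3 each). Genes with a site for the control mimic were higher. Over both times 4114 genes rose and 4257 fell.

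Of the genes with a miR-369-5p 8mer or 7mer-m8 site, CALM3 fell by 1.39 ± 0.07 (adjusted p 9.3e-10), RP2 by 1.66 ± 0.18, the ubiquitin ligase gene RNF111 by 1.39 ± 0.16, the splicing helicase DHX15 by 1.28 ± 0.08, the chaperone HSPH1 by 1.26 ± 0.07, CALHM5 by 1.22 ± 0.07, PLEKHA8 by 1.20 ± 0.15 and the cytoskeletal linker MACF1 by 1.18 ± 0.22. Against untreated cells at 24 h and 48 h, CALM3 was at -1.25 and -1.71, RP2 at -1.73 and -1.17, DHX15 at -1.40 and -1.01 and HSPH1 at -1.26 and -1.15. The smallest p-values among falls belonged to CBFB, a core-binding factor subunit (-1.69 ± 0.06), TFDP1, a partner of E2F factors (-1.25 ± 0.05), CD44 (-1.99 ± 0.08), CDCA8 (-1.64 ± 0.07) and PRC1 (-1.57), the last uncertain through shared exons. Among rises they belonged to CHST14 (1.69 ± 0.07), the m6A reader YTHDF2 (1.21 ± 0.05), TPD52L2 (1.17 ± 0.06) and TRAFD1 (1.10 ± 0.05), each with a cel-miR-67 site, and to TFPI2 (1.38 ± 0.07), with TPD52L2 at -0.042 and TFPI2 at -0.18 against untreated cells.

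The median of the 86 genes with a miR-369-5p site differed from matched lists by -0.22 at 24 h (permutation p 0.0006), -0.26 at 48 h (permutation p 0.0001, the smallest they can give) and -0.30 over both times (permutation p 0.0001). For the 28 genes with an 8mer the differences were -0.38 (permutation p 0.0009) and -0.50 at the 2 times (permutation p 0.0001). Against untreated cells the 86 genes were at -0.19 and -0.32 (permutation p 0.0001 each), and in the control mimic against untreated cells at 0.03 (permutation p 0.435) and -0.01 (permutation p 0.918). With the length and GC trend removed, the values against the control mimic were -0.14 (permutation p 0.0069) and -0.24 (permutation p 0.0001). Among 16369 7-mers, the 7mer-m8 GTCGATC ranked 73 from the lowest at 24 h and 2 at 48 h against the control mimic. Against untreated cells it ranked 3 and 2. The 7mer-A1 TCGATCA (150 genes) ranked 14 (TATTTAT lowest, z -5.39), 1, 1 and 1 in that order. By camera against all others, unmatched, the 86 genes were lower at 24 h (adjusted p 3.88e-07) and 48 h (3.02e-06), or 0.429 each with an estimated correlation.

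**Figure D5:**
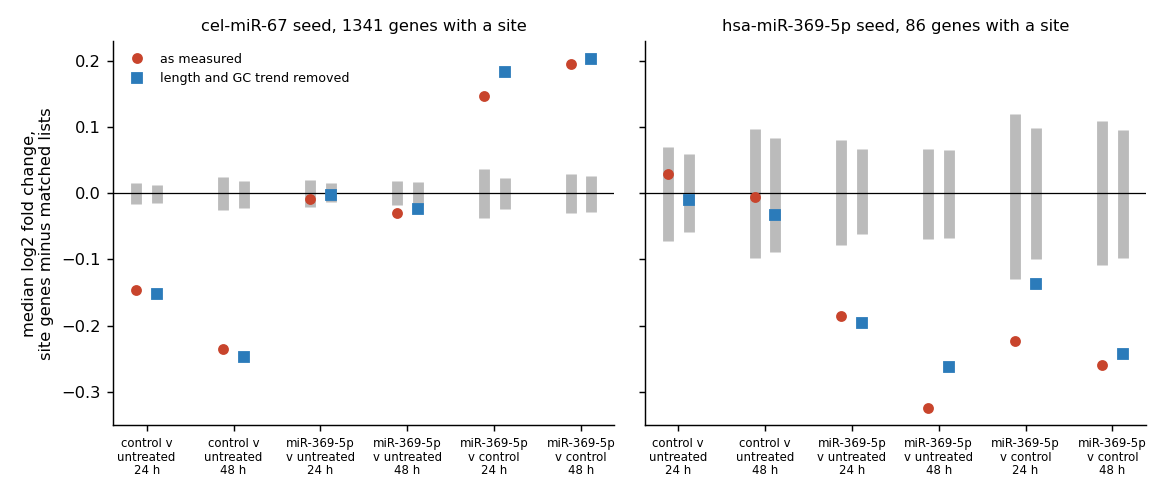
Difference of the median log2 fold change of genes with an 8mer or 7mer-m8 site from matched lists without one, by comparison and microRNA, as measured (circles) and with the length and GC trend removed (squares). Grey bars span 95% of matched lists. For miR-369-5p the difference is -0.22 and -0.26 in mimic against control mimic, and for cel-miR-67 it is -0.15 and -0.24 in control mimic against untreated.

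Sites of the control mimic lay in 1341 genes. These differed from matched lists by -0.15 at 24 h and -0.24 at 48 h in control mimic against untreated cells, and by 0.15 and 0.20 in miR-369-5p mimic against control mimic (permutation p 0.0001 each). Against untreated cells, the miR-369-5p mimic left them at -0.01 (permutation p 0.314) and -0.03 (permutation p 0.0006). The site GGTTGTG ranked lowest of all 7-mers in control mimic against untreated cells at both times (z -17.1 and -16.1) and highest between the mimics. Camera, unmatched, put these genes lower at 24 h between the mimics, with no call (adjusted p 0.505), and higher at 48 h (0.0481, or 0.696 with an estimated correlation). For miR-369-3p, 1929 genes were at -0.26 and -0.10 at 24 h and 48 h against the control mimic. With the trend removed they were at -0.07 and -0.06, still called, but their 7-mer GTATTAT had z -0.17 and -0.845. Against untreated cells they stayed lower at 24 h, with 0.04 at 48 h.

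Over both times 15 lists had a call, and 0 with an estimated correlation (adjusted p = 0.0665 to 0.56; 7 at an unadjusted p under 0.05, 24 by fry). G2/M genes fell in 69 of 73 cases (70 over the list alone; median -1.46, adjusted p 2.64e-33) and S phase genes in 39 of 58, with 1 rise (40 and 1 over the list alone; -0.69, 2.85e-11), while interferon genes rose in 39 of 47 (39 over the list alone; 0.91, 1.87e-18). Falls and rises were 23 and 5 of 36 for TGF-beta/BMP (-0.385, 0.00106), 27 and 8 of 52 for matrix (-0.38, 0.00383), 19 and 4 of 38 for cytoskeleton (-0.23, 0.00543), 15 and 3 of 32 for cholesterol (-0.24, 0.0142), 20 and 2 of 31 for silencing (-0.34, 0.00233) and 13 and 5 of 30 for coagulation genes (-0.21, 0.0475). The last call ended without control mimic replicate 1 of 24 h (adjusted p 0.067) and with the trend removed (-0.22, 0.176). Rises and falls were 21 and 4 of 35 for heme (0.485, 0.000299), 29 and 7 of 51 for autophagy (0.23, 0.00383), 75 and 0 of 78 for ribosomal proteins (0.52, 1.33e-11), 59 and 1 of 72 for oxidative phosphorylation (0.495, 4.12e-10), 9 and 1 of 15 for mitochondrially encoded (0.24, 0.0241) and 11 and 0 of 20 for sensing genes (0.31, 0.00239). Adjusted over the list alone, counts differed for matrix (28 and 8), cholesterol (16 and 3), ribosomal proteins (76), oxidative phosphorylation (64 and 1) and mitochondrially encoded genes (9 and 2). Of the 19 reported followed genes, 9 changed over both times, and HMOX1 (1.41 ± 0.09) and CDH5 (-0.81) were among them. With untreated cells as the reference 3202 genes were called, 2343 of the 8371 in the same direction and 133 in the opposite one.

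The difference between times asked which mimic effects were larger or smaller at 48 h than at 24 h. Interferon response genes gained most, S phase genes fell less at 48 h than at 24 h, and mesenchymal markers were lower at 48 h relative to 24 h. Against untreated cells S phase genes turned the other way, and the mesenchymal list lost its call (median -0.16, adjusted p 0.647). In all 333 genes differed, 163 upward and 170 downward. Scaling by library totals alone moved the median of all genes by 0.12 here, so list medians nearer to 0 than that have no firm direction.

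MX2 gained 3.43 ± 0.51, IFIT1 3.10 ± 0.44, MX1 2.93 ± 0.36, OAS3 2.82 ± 0.33 and IFI44L 2.56 ± 0.31 on the log2 scale, and the list rose in 30 of 47 cases (43 over the list alone; median 1.29, adjusted p 5.02e-56, adjusted p = 0.00227 with an estimated correlation). The largest losses were MMP1 (-1.83 ± 0.19), PLEK2 (-1.61 ± 0.28), UCP2 (-1.56 ± 0.20), the laminin gene LAMB3 (-1.54 ± 0.23) and the apelin receptor APLNR (-1.53 ± 0.33). S phase genes were higher in 19 of 58 cases (34 up and 2 down over the list alone; median 0.64, adjusted p 1.05e-21, adjusted p = 0.00831 with an estimated correlation), led by DTL, which controls replication licensing, (1.77 ± 0.13). Against untreated cells that list stood at -0.39. G2/M genes had no call (median -0.13, adjusted p 0.193). Endothelial-to-mesenchymal markers were lower in 4 of 19 cases (6 over the list alone; median -0.31, adjusted p 0.00021, adjusted p = 0.00878 with an estimated correlation), with MMP2 at -1.28 ± 0.13 and SNAI1 at -0.94 ± 0.17. Of the followed genes reported here, edgeR called 0, and 333 of all 16193 (2585 at an unadjusted p under 0.05). DESeq2 called 737 genes. The count fell to 147 without control mimic replicate 1 of 48 h, and lay at 159 to 221 without 6 further libraries (control mimic 24 h replicates 2 and 3, mimic 24 h replicate 3, control mimic 48 h replicates 2 and 3, mimic 48 h replicate 2) and at 525 without mimic replicate 3 of 48 h. Untreated cells as the reference gave 201 genes, of which 67 of the 333 were in the same direction.

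The control mimic was set against untreated cells to show what transfection of that mimic did on its own. At 24 h genes with a cel-miR-67 seed site fell, and interferon response genes rose as a list, a call lost with an estimated correlation (adjusted p = 0.173). HMGA2 (chromosome 12, 65824131 to 65966295), a chromatin protein of growing cells, rose from 41.8 CPM to 149.5 ± 12.4 CPM, and CHST14 fell from 41.3 ± 1.52 CPM to 12.6 ± 0.623 CPM (SD, n = 3 each). Some inflammatory genes fell. In all 350 genes rose and 336 fell.

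Interferon genes rose in 16 of 47 cases at 24 h (27 over the list alone), with a median of 0.49 and an adjusted p of 3.11e-15, or adjusted p = 0.173 with an estimated correlation. IFI44L (2.00 ± 0.23), MX1 (1.85 ± 0.26), MX2 (1.74 ± 0.38) and IFIT1 (1.72 ± 0.32) rose. HMGA2, which carries a weaker 7mer-A1 site for cel-miR-67, rose by 1.84 ± 0.12. The largest falls were CHST14 (-1.71 ± 0.10, adjusted p 1.3e-07), MNAT1 (-1.67 ± 0.15), NARS2 (-1.66 ± 0.14), NDUFB5 (-1.51 ± 0.17) and DPYSL3 (-1.50 ± 0.11), of which all but NDUFB5 carry a cel-miR-67 8mer. NF-kB inflammation genes fell in 7 of 41 cases and rose in 1 (10 and 2 over the list alone; median -0.24, adjusted p 8.06e-06, adjusted p = 0.173 with an estimated correlation), with CXCL8 at -0.83 ± 0.18, TRAF1 at -0.73 and the adhesion receptor SELE at -0.65 ± 0.17. HMOX1 fell by 0.57 ± 0.13. G2/M genes rose in 14 of 73 cases and fell in 3 (35 and 3 over the list alone; median 0.35, adjusted p 2.14e-16, adjusted p = 0.41 with an estimated correlation), with TOP2A at 0.81 ± 0.21 and KIF4A, a carrier of a cel-miR-67 8mer, at -0.95 ± 0.13. Silencing machinery genes rose in 3 of 31 cases (6 over the list alone; median 0.15, adjusted p 0.0011, adjusted p = 0.802 with an estimated correlation), DICER1 (chromosome 14, 95086228 to 95158010) by 1.15 ± 0.31 and AGO2 by 0.93 ± 0.24. Ribosomal protein genes (median -0.26, adjusted p 1.92e-07) and oxidative phosphorylation genes (-0.23, 6.76e-07) were lower as lists, with 2 single genes called in the latter and adjusted p = 0.802 for both with an estimated correlation. With the trend removed these 3 lists stood at 0.13, -0.14 and -0.08.

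Further calls at 24 h rested on single libraries. S phase genes (median 0.12, adjusted p 0.0277) lost theirs without untreated replicate 3 (0.24), cholesterol genes (0.12, 0.0453) and leukocyte markers (-0.27, 0.0364) without control mimic replicate 1 (0.314 and 0.0569), and autophagy genes (-0.12, 0.0376) without control mimic replicate 3 (0.142). Leukocyte markers had adjusted p = 0.554 and the other 3 lists adjusted p = 0.802 with an estimated correlation. With the length and GC trend removed, the calls of leukocyte markers (-0.09, 0.199) and autophagy genes (-0.05, 0.084) ended too. The count fell to 275 and 278 without untreated replicates 1 and 3, and to 293 and 335 without control mimic replicates 2 and 3.

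At 48 h cell cycle genes were lower with the control mimic than in untreated cells, and matrix, TGF-beta and mesenchymal genes were higher. The calls of G2/M (adjusted p = 0.101), TGF-beta/BMP (0.415) and matrix genes (0.538) were lost with an estimated correlation. Whether this differed from 24 h was not tested. The integrin gene ITGA8 (chromosome 10, 15513949 to 15720125) rose from 5.66 CPM to 52.3 CPM. HMOX1 fell from 92.4 ± 19.7 CPM to 30.9 ± 2.14 CPM (SD, n = 3 each). In all 1607 genes rose and 1902 fell, and in a fit of only these 6 libraries 2038 genes were called.

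S phase genes fell in 51 of 58 cases (54 over the list alone), with a median of -0.93 and an adjusted p of 4.72e-30, and the call held with an estimated correlation (adjusted p = 0.0038). G2/M genes fell in 59 of 73 (65 over the list alone; median -0.78, adjusted p 9.29e-28, adjusted p = 0.101 with an estimated correlation), among them KIF4A (-2.10 ± 0.14) and RACGAP1 (-1.96 ± 0.13). UHRF1 fell by 1.61 ± 0.12. ITGA8 rose by 3.21 ± 0.18 (adjusted p 2e-08), HMGA2 by 2.09 ± 0.12, ETV1 by 2.02 ± 0.20, LRATD1 by 1.95 ± 0.12 and IFI44L by 1.91 ± 0.23, while interferon genes as a list had no call (9 of 47 up and 4 down, 9 and 5 over the list alone; median 0.13, adjusted p 0.104). CA2 fell by 2.27 ± 0.18, and SULT1E1 (-2.66), TNFRSF6B (-2.36) and GCHFR (-2.34) are uncertain through shared or antisense exons.

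Mesenchymal markers rose in 9 of 19 cases at 48 h (10 up and 3 down over the list alone; median 0.40, adjusted p 0.00178, adjusted p = 0.0303 with an estimated correlation), with ZEB2 at 1.00 and the cadherin CDH2 at 0.96. TGF-beta/BMP genes rose in 12 of 36 cases and fell in 5 (16 and 7 over the list alone; median 0.34, adjusted p 0.0082, adjusted p = 0.415 with an estimated correlation), and matrix genes rose in 18 of 52 and fell in 4 (19 and 8 over the list alone; 0.33, 0.00813, adjusted p = 0.538 with an estimated correlation). PMEPA1 rose by 1.31 ± 0.14, INHBA by 1.13 ± 0.21 and MMP2 by 0.91 ± 0.09. Angiogenesis genes rose in 14 of 41 cases and fell in 5 (14 and 6 over the list alone; median 0.20, adjusted p 0.0225, adjusted p = 0.434 with an estimated correlation), with FLT1 at 1.09 ± 0.20 and KDR at 0.86 ± 0.20, a call lost without untreated replicate 3 (adjusted p 0.0576). Heme and NRF2 genes fell in 13 of 35 cases and rose in 2 (14 and 2 over the list alone; -0.35, 0.00178, adjusted p = 0.415 with an estimated correlation), with HMOX1 at -1.58 ± 0.13 and thioredoxin reductase TXNRD1 at -1.08. TFPI2 fell by 2.09 ± 0.10, CD34 by 1.46 ± 0.20 and CXCL8 by 1.11 ± 0.18. Heat shock genes (5 of 25 down, 8 over the list alone; -0.19, 0.00315) and ribosome biogenesis genes (2 of 43 up and 13 down, 2 and 15 over the list alone; -0.24, 0.00195) fell, with adjusted p = 0.449 and 0.394 with an estimated correlation. 

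Lists of short or long transcripts again moved with the length slope at 48 h, which was 0.167 to 0.195 in control mimic libraries and -0.147 to 0.207 in untreated ones. Ribosomal proteins (median -0.22, adjusted p 0.0225), oxidative phosphorylation (-0.30, 0.000168) and the silencing machinery (0.18, 0.00389) all lost their calls without untreated replicate 1 (0.548, with the median at 0.01, 0.161 and 0.0674). With an estimated correlation they had adjusted p = 0.854, 0.753 and 0.538. With the trend removed, ribosomal proteins stood at -0.01 (0.978) and the silencing machinery at 0.12 (0.102). Mitochondrially encoded transcripts fell in 7 of 15 cases (8 over the list alone; -0.34, 0.00251, adjusted p = 0.394 with an estimated correlation), a call lost with the trend removed (-0.15, 0.259).

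Untreated cells at 48 h were set against 24 h to show the change with time in culture alone. Cell cycle genes were lower at 48 h, and adhesion, matrix and lymphatic marker genes were higher. The adhesion (adjusted p = 0.213) and matrix (0.293) calls were lost with an estimated correlation. The adhesion receptor VCAM1 rose by 1.06 ± 0.17 (adjusted p 0.0037), and elastin, ELN, by 1.92 ± 0.21. In all 168 genes rose and 214 fell by edgeR in the fit of all libraries. In a fit of the 6 libraries alone edgeR called 0 genes, against 1998 at an unadjusted p under 0.05, and DESeq2 with all libraries called 808.

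G2/M genes fell in 44 of 73 cases with time (62 over the list alone; median -0.68, adjusted p 3.42e-56) and S phase genes in 16 of 58 (37 over the list alone; -0.42, 1.39e-24), with adjusted p = 0.0145 and 0.00978 with an estimated correlation. NDC80 fell by 0.98 ± 0.13 and CCNB2 by 0.99 ± 0.16. Lymphatic markers rose in 7 of 20 cases (10 up and 1 down over the list alone; 0.35, 2.95e-06, adjusted p = 0.0409 with an estimated correlation), with SEMA3D at 1.23 and the fatty acid carrier FABP4 at 0.98 ± 0.23. NF-kB inflammation genes rose in 6 of 41 cases and fell in 1 (9 and 3 over the list alone; 0.26, 0.00104, adjusted p = 0.213 with an estimated correlation), with IL33 at 1.17 ± 0.23, SELP at 0.72 ± 0.11 and ICAM1 at 0.47 ± 0.09. Matrix genes rose in 5 of 52 cases (7 up and 2 down over the list alone; 0.31, 8.34e-06, adjusted p = 0.293 with an estimated correlation). GDF7 (2.00 ± 0.21), the connexin GJA4 (1.67 ± 0.21), GFRA1 (1.34 ± 0.17) and the nitric oxide receptor subunit GUCY1A1 (1.29 ± 0.26) were the largest rises beside ELN, and PLEK2 (-1.16 ± 0.19) and TGFBI (-1.15 ± 0.16) the largest falls. Cholesterol genes fell in 3 of 32 cases (11 over the list alone; -0.30, 1.93e-08, adjusted p = 0.194 with an estimated correlation), and heme and NRF2 genes in 3 of 35 (10 down and 1 up over the list alone; -0.24, 7.44e-06, adjusted p = 0.234 with an estimated correlation), with HMOX1 at -0.58 ± 0.13. Ribosomal proteins (-0.22, 5.17e-07), oxidative phosphorylation (-0.23, 1.34e-08) and the silencing machinery (0.18, 0.0159) moved as lists with the length slope and had adjusted p = 0.636, 0.59 and 0.612 with an estimated correlation. Without 48 h replicate 3, ribosomal proteins (0.181), the silencing machinery (0.556) and keratinocyte markers (1 of 6 down; -0.26, 0.0192, then 0.162) lost their calls. Angiogenesis (0.14, 0.0192) and junction genes (0.06, 0.0297) lost theirs without 24 h replicate 1 (0.0949 and 0.0898), TGF-beta/BMP genes (0.13, 0.0168) without 24 h replicate 3 (0.0623) and immediate early genes (4 of 38 up, 1 down; 0.10, 0.0491) without 48 h replicate 1 (0.464). These 5 lists had adjusted p = 0.293, 0.331, 0.331, 0.302 and 0.361 with an estimated correlation, in the order named from keratinocyte markers on. Ribosome biogenesis (-0.12, 0.000636), mitochondrially encoded transcripts (-0.17, 0.016) and leukocyte markers (2 of 7 down; -0.35, 0.004) had adjusted p = 0.233, 0.293 and 0.194 in that test. With the trend removed the calls ended for angiogenesis (0.067), TGF-beta/BMP (0.067), junctions (0.0784), the silencing machinery (0.114) and mitochondrially encoded transcripts (0.419, median 0.13).

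The count of genes changed with time fell to 88, 150 and 214 without untreated 24 h replicates 1, 2 and 3, was 167 and 164 without 48 h replicates 2 and 3, and 815 without 48 h replicate 1.

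Calls of the miR-369-5p mimic against the control mimic at 24 h and 48 h, which share no library, coincided more often than n1 × n2 / N. Both times shared 1272 rises (418.7 by that product) and 1601 falls (523.3), and 12 and 18 genes moved in opposite directions. Across genes, which are not independent replicates, r was 0.477. The control mimic comparisons of both times likewise shared 278 rises (34.7) and 296 falls (39.5). Mimic against control mimic and control mimic against untreated cells share the control libraries. At 24 h, 281 genes rose in the first and fell in the second (65.0) and 281 did the reverse (72.9), with a covariance of -0.24 against -0.0674 in simulated data with no differences. At 48 h, 1046 and 1003 genes did so (254.3 and 249.4), with a covariance of -0.232 against -0.071. Part of these excesses may come from the shared control libraries, which cannot be split into parts of at least 2. The miR-369-5p mimic and the control mimic, each against the same untreated libraries, shared 279 rises (84.4) and 475 falls (160) at 48 h, with a covariance of 0.126 against 0.0693 in simulated data and with 131 (135.2) and 77 (99.8) genes in opposite directions, and 40 rises (7.5) and 35 falls (15.7) at 24 h, where 57 genes fell with the former and rose with the latter (16.4) and 7 did the reverse (7.2), with a covariance of 0.00839 against 0.0693.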

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

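The tests of seed-directed repression by the control mimic, of library size and of a few abundant genes were chosen after the results were seen.

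A test of the difference between times singled out 10 genes and 16 lists whose change with the miR-369-5p mimic over the control mimic was not the same at 48 h and 24 h. The differences were 3.43 for MX2, 3.10 for IFIT1, 2.93 for MX1, 2.82 for OAS3 and 2.56 for IFI44L, and -1.83 for MMP1, -1.61 for PLEK2, -1.565 for UCP2, -1.54 for LAMB3 and -1.535 for APLNR, on the log2 scale. Among lists, the median difference was 1.29 for the type I interferon response, 0.636 for S phase genes (adjusted p 1.05e-21), -0.313 for endothelial-to-mesenchymal markers and 0.692 for RNA and DNA sensing (adjusted p 9.74e-11), and these 4 calls held with an estimated correlation. Against untreated cells S phase genes reversed to -0.389 and mesenchymal markers lost the call (0.647).

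For ribosomal proteins it was -0.41 (adjusted p 2.68e-11), for oxidative phosphorylation -0.275 (4.32e-05), for cytoskeleton and SRF/YAP targets -0.193 (0.00503) and for extracellular matrix -0.152 (0.00618). Ribosome biogenesis stood at 0.186 (0.00276), hypoxia and glycolysis at -0.0928 (0.0198), immediate early genes at -0.214 (0.0219), senescence at -0.411 (0.0237), TGF-beta/BMP at -0.151 (0.0248), angiogenesis at -0.176 (0.0478), coagulation at -0.149 (0.0489) and the heme and NRF2 response at 0.148 (0.0489). In the order named, these 12 lists had adjusted p = 0.473, 0.548, 0.141, 0.456, 0.324, 0.439, 0.393, 0.393, 0.393, 0.432, 0.291 and 0.48 with an estimated correlation. Without mimic replicate 3 of 48 h the calls of coagulation (0.18), heme (0.367), TGF-beta/BMP (0.18) and matrix genes (0.214) ended. Those of hypoxia (0.0565), senescence (0.0687) and immediate early genes (0.0631) ended without mimic 24 h replicate 1, mimic 24 h replicate 2 and control mimic 24 h replicate 3, and those of angiogenesis (0.234) and ribosome biogenesis (0.0836) without control mimic 24 h replicate 1. After removal of the length and GC trend, coagulation (0.0667), angiogenesis (0.146), senescence (0.0964) and immediate early genes (0.138) lost their calls. Against untreated cells ribosome biogenesis (-0.125), heme (-0.158), angiogenesis (0.065) and TGF-beta/BMP (0.00475) turned direction.

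Interferon response genes were higher with the miR-369-5p mimic than with the control mimic at 48 h by a median of 1.6, and the mean of the list lay at 5.567 log2 CPM or more in each mimic library and at 4.182 or less in each control mimic library. A length and GC trend as the whole cause is argued against by a median of 1.62 with the trend removed. A single library is argued against by a lowest median of 1.59 when any 1 of the 6 was left out. A response to the miR-369-5p duplex itself, through its sequence or through its preparation, may underlie the difference. These were not tested against each other.

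Genes with a cel-miR-67 seed site were lower with the control mimic than in untreated cells. The length and GC trend is argued against as the whole cause, as with it removed the difference from matched lists was -0.152 at the time nearer to 0. The site 7-mer had rank 1 from the lowest of 16369 in control mimic against untreated cells at both times, and ranks 5013 and 1614 in miR-369-5p mimic against untreated cells. Repression directed by the seed of the control mimic is a candidate explanation, found and tested on the same data. In that case part of the rises of the miR-369-5p mimic over the control mimic may reflect the control, as for CHST14 at 0.06 against untreated cells.

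At 24 h 6504 genes differed between the mimics. The length and GC trend as the whole cause is argued against by 6311 calls with it removed, of which 4280 were among the 6504 in the same direction and 26 in the opposite one. A difference in depth cannot be told apart, since totals ran from 34.33 to 35.66 M counts in the mimic libraries, and of the control mimic libraries 1 held 36.23 M counts and the others 32.42 and 29.9 M counts. A few abundant genes are argued against by a difference of 0.303 percentage points in the share of the 10 most abundant genes. Effects of both mimics may add up in this count, since 1108 genes were called against untreated cells, and the shares of each were not tested.

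Other splits of the same libraries were tried for each count of genes. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and the real split had the most calls each time. The real counts and the highest of the others were 6504 and 0 for the mimic at 24 h, 4678 and 1 at 48 h, 686 and 0 for the control mimic at 24 h, 3509 and 0 at 48 h, and 382 and 0 for time. For the mean over both times only the real split of 100 reached 8371 (highest other 4328), the smallest share possible. For the difference between times 7 of 100 splits were as large (333, highest other 4599). Splits here may carry effects of time or treatment, so the count cannot decide on chance.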

How the results depend on the processing

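Removal of the length and GC trend was chosen after seeing the data, and all other alternatives were planned. Of 148 counts of genes under alternatives, 101 stayed within 1.5 times the reported count and 47 did not. Named genes kept direction and side of the threshold in 6887 cases, were no longer called in 427, newly called in 71 and reversed in 18. Lists did so in 995 cases, lost the call in 230 and reversed by the direction of the test in 9. Seed site differences did so in 135 cases. With replicate number as a block the counts were 6364, 4615, 8273, 331, 617, 3484 and 426 for the 7 comparisons in the order of the methods. Deviations of same-numbered replicates correlated between groups from -0.445 to 0.511, with no other pairs tested, so pairing is open. The cause was not tested for any change below unless stated.

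Untreated cells as the reference gave 1108, 2212, 3202 and 201 genes for the mimic at 24 h, at 48 h, over both times and for the difference, and 9 lists at 48 h. An absolute log2 fold change of at least 1 left 1047, 1116, 1065, 127, 89, 705 and 81 genes, and an adjusted p under 0.01 left 3075, 2795, 117, 269, 1868 and 112 (all but the mean over both times), by the stricter threshold itself. DESeq2 called 737 genes for the difference, 1242 for the control mimic at 24 h and 808 for time. With the length and GC trend removed, 1256 genes were called for the difference, 2020 and 5315 for the control mimic at 24 h and 48 h, and 1331 for time. A fit of only the groups compared called 2038 genes for the control mimic at 48 h and by edgeR 0 for time, against 1998 at an unadjusted p under 0.05. Share of rises among calls moved from 46.3% to 57.3% at 48 h and from 48.9% to 75.3% for the difference with library totals alone, from 48.2% to 31.5% at 24 h and from 48.9% to 23.9% for the difference with untreated cells as the reference, and from 51% to 62.5% for the control mimic at 24 h with the trend removed.

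Leaving out 1 library gave 3407 (without control mimic replicate 3) to 7352 (without control mimic replicate 1) genes for the mimic at 24 h, with 3715 without control mimic replicate 2 and 3776 without mimic replicate 3. For the difference it gave 147 (without control mimic 48 h replicate 1) to 525 (without mimic 48 h replicate 3), with 159, 170 and 183 without control mimic replicates 2 and 3 and mimic replicate 3 of 24 h, and 172, 175 and 221 without control mimic replicates 2 and 3 and mimic replicate 2 of 48 h. For the control mimic at 24 h the range was 275 (without untreated replicate 1) to 744 (without control mimic replicate 1), with 278, 293 and 335 without untreated replicate 3 and control mimic replicates 2 and 3. For time it was 88 (without untreated 24 h replicate 1) to 815 (without untreated 48 h replicate 1), with 150 and 214 without replicates 2 and 3 of 24 h and 167 and 164 without those of 48 h. The number of lists ran from 10 (without mimic 24 h replicate 2) to 22 (without mimic 48 h replicate 1) for the difference and from 6 (without untreated replicate 3) to 10 for the control mimic at 24 h. Ribosomal proteins in the control mimic at 48 h ran from -0.391 to 0.0123 (adjusted p 0.548), the latter without untreated replicate 1.

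Camera with an estimated correlation called 2, 1, 0, 4, 0, 2 and 3 lists in the 7 comparisons. At an unadjusted p under 0.05 it called 7 lists over both times and 3 for the control mimic at 24 h, where it called 0 after adjustment. Fry called 18 lists at 24 h, 24 over both times, 7 for the difference, 4 for the control mimic at 24 h and 11 for time.

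With untreated cells as the reference, the test of the silencing machinery at 48 h turned upward at a median of -0.0443 without a call, and list medians for the difference reversed to -0.158 for the heme response, 0.065 for angiogenesis, 0.00475 for TGF-beta/BMP, -0.389 for S phase (adjusted p 7.76e-08) and -0.125 for ribosome biogenesis. Medians of matrix (0.0751) and coagulation genes (0.0541) also changed sign there, while their tests still pointed downward without a call. Genes reversed at 24 h were NARS2 (-0.21) and DICER1 (0.092), at 48 h HMOX1 (-0.11), TFPI2 (-0.54), STC1 (0.070), CD34 (-0.14), CXCL8 (-0.18) and F3 (1.03, adjusted p 0.00959), over both times TPD52L2 (-0.042), TFPI2 (-0.18), CXCL8 (-0.34), F3 (0.85) and KDR (0.13), and for the difference HELLS (-0.065) and HMOX1 (-0.90). Seed site differences reversed to -0.00826 and -0.0299 for cel-miR-67 at 24 h and 48 h and to 0.0375 for miR-369-3p at 48 h. With the length and GC trend removed, mitochondrially encoded transcripts, called before, turned to -0.0758 over both times and 0.127 for time, neither called. CCL2 turned to -0.33 at 24 h and -0.24 over both times and ANGPT2 to 0.14 over both times, all called only then. It also brought calls of senescence (-0.35) and ribosome biogenesis (-0.132) over both times, and of G2/M (-0.149), p53 (-0.0864), heat shock (0.153) and mitochondrial genes (0.288) for the difference. With any site down to the 6mer, the miR-369-5p difference between times became -0.0354 (permutation p 0.0324), past the threshold, and the cel-miR-67 difference at 24 h fell short of it at 0.0202 (permutation p 0.0509).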

Other observations

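The test of competition with the cells' own microRNAs was chosen after the result was seen.

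Against untreated cells, the miR-369-5p mimic moved the interferon list by medians of 0.774 at 24 h (6.46e-22) and 1.58 at 48 h (2.04e-59). The control mimic also raised the list at 24 h, so 0.774 is not specific to miR-369-5p. Brackets hold camera's adjusted p (preset correlation). RNA and DNA sensing genes had a median of 0.73 at 48 h (1.73e-07). Ribosome biogenesis genes were lower at both times, at -0.123 (0.00315) and -0.225 (0.000295), with no call between the mimics (0.0869 and 0.846). Heat shock genes were lower at 48 h (-0.218, 0.00705), as were hypoxia and glycolysis genes (-0.204, 0.0181). TGF-beta/BMP genes stood at -0.242 (0.0214) and -0.281 (0.0288), and cytoskeleton and SRF/YAP targets at -0.186 (0.0418) and -0.234 (0.0163), at 24 h and 48 h. At 24 h immediate early genes were higher (0.172, 0.0124) and NF-kB inflammation genes lower (-0.166, 0.00443). Also higher at 24 h were ribosomal proteins (0.465, 3.14e-14), oxidative phosphorylation (0.408, 9.24e-10), heme and NRF2 (0.313, 0.000346) and autophagy genes (0.162, 0.00271). Endothelial identity genes had no call at 24 h or 48 h (0.838 and 0.676).

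Competition of the control mimic with the cells' own microRNAs for the silencing machinery was tested as a hypothesis. It predicts that genes with sites for microRNAs known to be abundant in endothelial cells rise with the control mimic. The sites of 24 such seeds had a mean z of 1.87 at 24 h and 1.56 at 48 h in control mimic against untreated cells, where matched random sets of 7-mers averaged -0.184 and -0.00234, above all 10000 random sets both times (permutation p 0.0001, the smallest they can give). After removal of the length and GC trend the values were 0.488 and 0.472 against -1.49 and -1.13. The same seeds had a mean z of 2.31 against 0.892 in untreated cells at 48 h against 24 h, where no mimic was added, also above all random sets. In miR-369-5p mimic against untreated cells it was 0.853 against 0.429 at 24 h (above 98.3% of random sets) and 1.1 against 0.208 at 48 h (above all). Between the mimics it was -0.609 against 0.436 at 24 h (below all) and -0.316 against 0.185 at 48 h (permutation p 0.0107). Since the measure also moves where no mimic was added, competition cannot be told apart from other changes in these genes.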
